A study of Mus musculus with 12 samples.

How the data were processed

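Bulk RNA of hand-picked pancreatic islets had been sequenced in 12 libraries, 3 each of female control, female knockout, male control and male knockout. Groups, sexes and replicate numbers were taken from the labels. The labels name no Cre in the controls, so an effect of the Cre transgene falls together with the genotype. They do not say that each library came from 1 separate animal, and the p-values below measure the spread between these libraries.

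Per the submitters' processing notes, reads were checked with FastQC 0.11.9, trimmed with Trim Galore 0.6.7, aligned with STAR 2.7.3a to GRCm39 (mm39) and counted per gene with featureCounts, for which no version is given. The strand setting, the annotation release and the rule for reads that fit several genes are not stated. The signal values per library, as deposited by the authors in 1 table per sex, were read counts divided by 1 size factor per library (DESeq2 normalized counts), scaled over the 6 libraries of that sex. The log2 fold changes deposited by the authors, knockout over control, were DESeq2 maximum likelihood estimates per the file's description sheet. The p-values deposited by the authors were those of the DESeq2 Wald test with Benjamini-Hochberg adjustment per the same sheet, which gives neither a version nor a model. Genes with fewer than 10 reads in total were absent from the tables. The deposited subsets picked by fold change and p held no further values and were not used here.

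The tables held 24631 genes in females and 24474 in males after removal of 79 and 73 repeated entries of a gene, and 40 and 50 genes had no name and kept their identifier. Whole reads were recovered from 100% of the values within a tolerance of 0.001, by dividing each library's values by its smallest step. Names and coordinates came from the tables themselves (GRCm39), since the reference at hand was of another build. Gene length was the annotated span.

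The libraries held 19759712 to 56086810 assigned reads. Between libraries of 1 group, genes with at least 20 reads in the pair had a mean squared difference 25.3 to 263 times that of counting noise, so that the spread between libraries, and not counting, set the precision for most reads. Male control 2 was the shallowest and had the fewest genes with reads, and it was kept in every comparison, with the values without it given.

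The design, fixed before the data were examined, foresaw edgeR for whole counts and limma for normalized values. The tables held normalized values, so limma was the main test and edgeR on the recovered reads an alternative. Values were taken as log2 of the normalized count plus 1, genes with a mean of at least 10 over the 6 libraries were tested, and limma-trend (limma 3.58.1 in R 4.3.3, empirical Bayes with trend and robust settings) was fitted per sex with genotype as the sole term. This tested 18142 genes in females and 18010 in males. The sex difference of the knockout effect was the interaction of sex and genotype over all 12 libraries and the 17330 genes tested in both. Genes were called at a Benjamini-Hochberg adjusted p below 0.05, and every adjusted p of a gene in the report is from limma unless another tool is named. Overlaps of calls were set against the product of both counts over the genes tested in both, with odds ratios from Fisher's exact test, and fold changes were correlated across genes.

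There were 31 gene lists, written from general knowledge of islet biology before the data were examined. Of these, 10 were primary: beta cell transcription factors, beta cell function, alpha markers, markers of delta, PP and epsilon cells, disallowed genes, progenitor and dedifferentiation genes, exocytosis, ion channels, H2B ubiquitination and the Islet-1 complex. Another 12 were secondary: H3K4 and H3K79 methyltransferases, the unfolded protein response, p53 targets, cell cycle, replication-dependent histones, glycolysis, oxidative phosphorylation, mitochondrially encoded genes, interferon response, antigen presentation, immediate early genes and lactogen response. The methyltransferase list also held subunits and partners of these enzymes, such as Rbbp5, Mllt3 and Kdm6a. The remaining 9 held markers of acinar, duct, endothelial, stellate, macrophage, lymphocyte, Schwann, erythrocyte and adipocyte cells. Lists with at least 3 tested members were tested with camera (preset correlation between genes 0.01), again with the correlation estimated per list, and with fry, adjusted over the lists. Camera compares a list with the other genes, so it does not test whether the list as a whole differs from 0. For each list the calls adjusted over its members alone were counted too.

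Genes named in the text followed a rule set before the data were examined. It takes 14 fixed genes (Rnf20, Rnf40, Isl1, Ldb1, Pdx1, Mafa, Nkx6-1, Ucn3, Slc2a2, Ins1, Ins2, Gcg, Sst and Ppy). It takes per sex the 6 largest rises and 6 largest falls among called genes with a mean at or above the median of tested genes and groups that do not overlap, without predicted, Rik, mitochondrial, ribosomal pseudogene or unnamed genes. It adds the 2 called members with the smallest p from each primary list, 1 from each other list with at least 3 called members, and the 4 genes with the smallest adjusted p for the sex difference. Other genes named as list members or in the sex difference were chosen after their values were seen, and some genes the rule or the lists would name are not reported here.

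Alternatives set before the data were examined were TMM and quantile scaling, scaling without acinar genes, the acinar level as a covariate, DESeq2 1.42.0, limma-voom, no low-value filter, pseudocounts of 0.5 and 5, a 2-fold threshold, a fit of all 12 libraries, the replicate number as a block, and leaving out each library. The edgeR 4.0.16 quasi-likelihood test, the list tests of the sex difference and the counts of called members without control 2 of each sex were added after the data were seen. A DESeq2 fit to the recovered reads called the same 4371 and 3733 genes as the deposited adjusted p in females and males.

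The tests were tested on simulated data, with 200 genes changed in counts drawn at the real means and depths. In the female simulation (18115 genes) limma called 8.96%, 46.3% and 86.4% of genes changed 1.5-, 2- and 4-fold, with 11 of 105 calls false. In the male simulation (17939 genes) it called 2.99%, 38.8% and 56.1%, with 8 of 73 calls false. For the sex difference (17330 genes) it called 0%, 11.9% and 48.5%, with 2 of 42 calls false. DESeq2 had 49 of 158 calls false in the female and 60 of 150 in the male simulation. A planted list was called and 0 of 30 unchanged lists were called by camera in each sex. The simulated genes were drawn independently of each other, so false calls of lists with correlated genes were not measured. Far fewer genes were changed than were called in the real data, which makes the adjusted threshold stricter. The shares of calls above need therefore not hold for the real comparisons. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.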

Results

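RNA was sequenced from hand-picked pancreatic islets of mice in which tamoxifen deletes Rnf20 in cells expressing Pdx1-driven CreER, and from flox controls that carry no named Cre. Rnf20 encodes a ubiquitin ligase that acts with its partner Rnf40 to place 1 ubiquitin on histone H2B in transcribed genes. Every mouse had received tamoxifen by gavage 5 times at 4 weeks of age, at 150 ug per g. There were 4 groups of 3 libraries: female control, female knockout, male control and male knockout. The libraries held 41925150, 36968894 and 35489685 assigned reads in female controls, 39854365, 32557635 and 41739999 in female knockouts, 47505864, 19759712 and 56086810 in male controls, and 35922352, 41327854 and 41572365 in male knockouts. Values are normalized counts, scaled by the submitters within each sex, and a gene was called when its adjusted p was below 0.05. Male control 2 stood apart: 17701 genes had reads in it, while the other male libraries would give 21496 to 22666 genes at its depth. In it 1596 tested genes were at 0, compared with at most 200 in any other library. Ins1 and Ins2 together took 13.4% of reads in female controls and 10.6% in female knockouts, and 16.3% and 12.3% in the male groups. Acinar genes took 4.38 ± 1.83% (SD, n = 3) in female controls and 2.28 ± 0.366% in female knockouts, and 3.73 ± 3.77% and 3.57 ± 2.39% in males. Mitochondrially encoded genes took 2.31 ± 0.270% in female controls and 3.55 ± 0.0898% in female knockouts, and 1.73 ± 0.210% and 2.59 ± 0.707% in males.

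The first comparison asked how far the targeted transcript was reduced in each library. Rnf20 (ENSMUSG00000028309, chromosome 4, 49632006 to 49656887) was at 3589, 4032 and 4340 normalized counts in female controls and at 1877, 2000 and 1927 in female knockouts. It fell 2.05-fold in females (log2 fold change -1.04, standard error 0.10, n = 3 per group, adjusted p = 6.35e-04). In males Rnf20 was at 3812, 3409 and 4058 in controls and at 1519, 1373 and 1436 in knockouts, a 2.60-fold fall (log2 fold change -1.38, standard error 0.12, n = 3 per group, adjusted p = 7.91e-04). Every knockout library lay below every control library in both sexes. Its partner ligase gene Rnf40 was not called in females (log2 fold change 0.18, adjusted p = 0.261) or in males (log2 fold change 0.29, adjusted p = 0.175). The log2 effect on Rnf20 was lower by 0.34 in males than in females, and this difference was not called (adjusted p = 0.567). The values are for the whole gene and for all cells of the islet, so reads from the undeleted part of the gene and from cells without Cre are in them. The panels of counts per library show Rnf20 beside 7 islet genes.

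**Figure D1:**
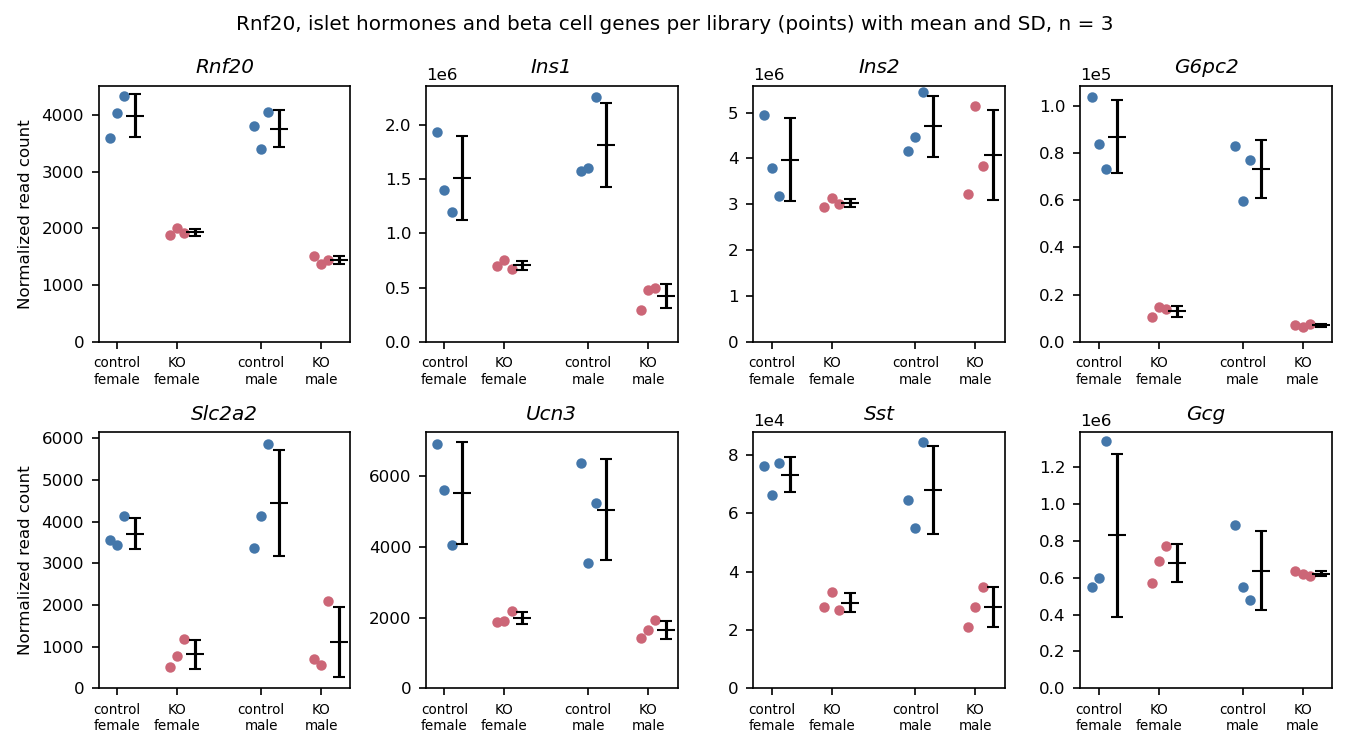
Normalized counts (y axis, linear, from 0) of Rnf20, Ins1, Ins2, G6pc2, Slc2a2, Ucn3, Sst and Gcg in female and male control and knockout groups (x axis), with 1 point per library and a bar for the group mean with its SD. G6pc2 had means of 86911 and 12992 in female controls and knockouts and of 73157 and 6986 in males.

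The female comparison asked which islet transcripts depend on Rnf20 in females. Beta cells turn glucose into insulin release through glucose entry, glucose metabolism and granule exocytosis. G6pc2, the beta cell glucose-6-phosphatase (ENSMUSG00000005232, chromosome 2, 69041417 to 69058185), fell 6.69-fold, from 86911 ± 15403 to 12992 ± 2268 normalized counts (SD, n = 3 per group; log2 fold change -2.74, standard error 0.17, adjusted p = 1.96e-04). Slc2a2, which encodes the glucose transporter GLUT2 (ENSMUSG00000027690, chromosome 3, 28752052 to 28785508), fell 4.80-fold, from 3711 ± 374 to 818 ± 348 (log2 fold change -2.26, standard error 0.29, adjusted p = 0.00335). Ucn3, a peptide of mature beta cells, fell 2.71-fold (log2 fold change -1.44, standard error 0.19, adjusted p = 0.00226). The insulin gene Ins1 fell 2.10-fold, from 1508200 ± 383780 to 704220 ± 43347 (log2 fold change -1.07, standard error 0.18, adjusted p = 0.00534), and Ins2 was not called (log2 fold change -0.37, standard error 0.17, adjusted p = 0.166, and 0.0462 without female control 3). Sst, the delta cell hormone, fell 2.50-fold, from 73283 ± 5962 to 29403 ± 3283 (log2 fold change -1.32, standard error 0.11, adjusted p = 4.67e-04). The alpha cell hormone Gcg and the PP cell hormone Ppy were not called (log2 fold change -0.18 and -0.39, adjusted p = 0.764 and 0.661). Ins1 and Ins2 share sequence, and how reads that fit both were assigned is not stated. Under quantile scaling the rank of Ins1 fixes its value, which gives no difference between the groups.

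In females 3745 of 18142 tested genes were called, with 1796 higher and 1949 lower in the knockout. The count was 2069 without control 2, 2421 without knockout 1 and 1847 without knockout 2, and 1118 genes, 613 higher and 505 lower, also differed at least 2-fold. Among the largest rises were the noncoding RNA Miat (15.8-fold), Wdr72 (14.3-fold), the channel regulator Stac2 (8.37-fold), the corepressor Rcor2 (6.49-fold), the histone gene H4c8 (6.24-fold) and the forkhead factor Foxo6 (4.71-fold). Among the largest falls were the neuropeptide Vip (7.99-fold), the metallothionein Mt1 (7.23-fold), the synuclein Sncg (5.63-fold) and the zinc finger factor Ovol2 (5.56-fold), each called at adjusted p = 0.00860 or less with its groups not overlapping, which chance gives for 10% of genes at 3 against 3. An immunoglobulin kappa segment on chromosome 6 (ENSMUSG00000094345) was at 44.5, 3490 and 150 in controls and at 0, 1.11 and 1.67 in knockouts. Its call was lost under edgeR (adjusted p = 0.0793), under voom, without the low-value filter, and without control 3 or any knockout library (adjusted p = 0.0617 to 0.0996).

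Beta cell transcription factors moved both ways in females. Over all the gene lists 109 of 168 called genes kept their call in every fit without 1 library, and an example gene that lost it is given with the libraries. Of 22 tested, 7 fell and 5 rose (7 and 6 adjusted over the list alone), and the list test was not called (camera adjusted p = 0.858, and adjusted p = 0.953 with an estimated correlation). The numbers that rose were 2 without control 2, 2 without knockout 2 and 3 without knockout 3. St18 (log2 fold change -1.82), Mnx1 (-1.33), Pdx1 (-1.07), Neurod1 (-0.82) and Pax6 (-0.72) fell, and Glis3 (0.95) and Foxo1 (0.59) rose. Pdx1 specifies the pancreas and drives insulin transcription, and it went from 3822 ± 625 to 1817 ± 276 (SD, n = 3, adjusted p = 0.00284). The insulin activator Mafa fell 2.33-fold (log2 fold change -1.22, adjusted p = 0.0261), a call lost without control 1, control 3 or knockout 2 (adjusted p = 0.0552 to 0.0785) and with the acinar level as a covariate (log2 fold change -0.94). Isl1, whose protein binds the cofactor Ldb1, fell 1.38-fold (log2 fold change -0.47, adjusted p = 0.0151), and its call was lost without knockout 1 or knockout 2 (adjusted p = 0.0611 and 0.0630) and with the acinar covariate (adjusted p = 0.0994). Nkx6-1 rose 1.55-fold (log2 fold change 0.63, adjusted p = 0.0382), and its call was lost without control 2, control 3 or any 1 knockout library (adjusted p = 0.0534 to 0.121) and with the acinar covariate (adjusted p = 0.0621).

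Genes of beta cell function and maturity fell in females: 22 of 36 tested fell and 0 rose by limma over all genes (22 and 2 adjusted over the list alone), and 1 rose without knockout 1. The median log2 fold change was -0.88 (camera adjusted p = 5.67e-09, and adjusted p = 0.352 with an estimated correlation). Besides the genes above, the fatty acid receptor Ffar1 (-1.84), the zinc transporter Slc30a8 (-1.67), the amyloid peptide Iapp (-1.48) and the prohormone convertase Pcsk1 (-1.38) had lower log2 values. Of 36 insulin granule exocytosis genes 12 fell and 2 rose (15 and 2 adjusted over the list alone; camera adjusted p = 1.95e-04, and adjusted p = 0.352 with an estimated correlation). Among them were the synaptotagmin Syt4 (-1.56), the vesicle protein Sv2a (-1.48) and the small GTPase Rab27a (-1.07), which fell, and Snap25 (0.63) and Doc2b (1.10), which rose. Ion channel genes went both ways, with 5 of 29 lower and 5 higher (5 and 7 adjusted over the list alone; camera adjusted p = 0.544, and adjusted p = 0.943 with an estimated correlation). The KATP channel subunit Kcnj11 (-0.72) and the calcium pump Atp2a2 (-0.75) fell, and the cation channel Trpm2 (2.03) rose, although Atp2a2 was not called under quantile scaling (adjusted p = 0.322). The channel genes that rose were 2 without control 1, control 2 or knockout 2, and 3 without knockout 1 or knockout 3. Beside these lists, the acinar markers had a median log2 fold change of -1.01 in females (-1.42 without control 2 to -0.73 without control 1). The endothelial markers had 0.24 (0.12 without knockout 1 to 0.31 without knockout 3). The 5 erythrocyte markers had 1.70 (0.69 without control 3 to 2.65 without control 1), and the macrophage markers had -0.48 (-0.67 without knockout 3 to -0.12 without control 2). The stellate markers had 0.19 (-0.00 without knockout 3 to 0.52 without knockout 2, and -0.20 with the acinar level as a covariate).

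Markers of immature or other endocrine cells moved gene by gene in females. Of 21 endocrine progenitor and dedifferentiation genes 7 rose and 2 fell (the same counts adjusted over the list alone; camera adjusted p = 0.0433, and adjusted p = 0.352 with an estimated correlation). The camera call was lost without control 1, control 3 or knockout 3 (adjusted p = 0.0507, 0.1105 and 0.0720) and under quantile scaling (adjusted p = 0.0661). Pax4, a factor of endocrine progenitors, had 0 reads in the female controls and 93 in the knockouts, at least 26.8-fold higher over a floor of 3 reads per group. Neurog3, which starts endocrine differentiation, rose 4.17-fold from 61.2 ± 11.4 to 259 ± 48.2 (SD, n = 3, adjusted p = 0.00116, and 0.264 in the fit of all 12 libraries). The hormone gene Cck (2.33) also rose in log2 terms. Of the 2 that fell, Asb11 (-2.12) kept its call and Sox11 (-1.16) lost it without control 1, control 2 or any 1 knockout library (adjusted p of at most 0.0887). Of 30 disallowed genes, which mature beta cells keep low, Acot7 alone was called (-1.16), lower (1 adjusted over the list alone; camera adjusted p = 0.722, and adjusted p = 0.945 with an estimated correlation), and 1 more was called higher without control 2. Of 20 alpha cell markers 1 rose, Gc (0.74), and 2 fell, Sphkap (-0.61, adjusted p = 0.0636 with the acinar covariate) and Slc7a14 (-0.55), with the same counts adjusted over the list alone (camera adjusted p = 0.750, and adjusted p = 0.945 with an estimated correlation). Without control 3, 6 alpha markers were higher, and without knockout 3, 2 were. Without knockout 1 or knockout 3 the call of Slc7a14 was lost (adjusted p of at most 0.0565), which left 1 lower. Of 16 delta, PP and epsilon markers 3 fell, Sst, Ghsr (-1.71) and Hhex (-0.52), and Crhr2 rose (2.79, adjusted p = 0.120 in the fit of all 12 libraries), or 5 and 1 adjusted over the list alone (camera adjusted p = 0.434, and adjusted p = 0.894 with an estimated correlation). The call of Hhex was lost without any library but knockout 1 (adjusted p of at most 0.123), and 2 of these markers were higher without knockout 3.

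Lists of chromatin, cell cycle and p53 genes were tested next in females. Of 18 genes of H3K4 and H3K79 methyltransferases and their partners 6 rose and 0 fell by limma (8 and 0 adjusted over the list alone). Camera gave adjusted p = 0.00700, and adjusted p = 0.438 with an estimated correlation. Among the rises were the partner gene Mllt3 (1.03) and the methyltransferase gene Kmt2c (1.01), the 2 called without control 2 or any 1 knockout library. Of 29 replication-dependent histone genes 10 rose and 0 fell by limma (13 and 0 adjusted over the list alone; camera adjusted p = 3.70e-06, and adjusted p = 0.631 with an estimated correlation). They included the linker histones H1f3 (2.61), H1f4 (2.35) and H1f2 (1.64) and the core histone H3c15 (2.34), while edgeR called 11 higher. Histone genes of each class are close in sequence. Of 33 cell cycle genes 4 fell and 2 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.722, and adjusted p = 0.945 with an estimated correlation). The replication genes Mcm2 (-1.09), Pcna (-0.78), Rrm1 (-0.47) and Mcm4 (-0.45) fell and Mybl2 (0.97) and Aurka (0.92) rose. Aurka lost its call without control 2, knockout 2 or knockout 3 (adjusted p of at most 0.0811), and Mcm4 without control 2, control 3, knockout 2 or knockout 3 (adjusted p of at most 0.113). Of 15 Islet-1 complex genes 5 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.135, and adjusted p = 0.564 with an estimated correlation). Ldb1 rose 1.65-fold (0.72, adjusted p = 0.00313) and Ssbp2 1.93-fold (0.95). In the list 3 genes rose without control 2, control 3, knockout 1 or knockout 3 and 2 without knockout 2. The fall of Isl1 was the 1 lower call, with 2 lower without control 3 and none by limma without knockout 1 or knockout 2. Of 23 H2B ubiquitination and deubiquitination genes 3 fell, Rnf20, Usp51 (-1.20) and Eny2 (-0.66), and 3 rose (3 and 4 adjusted over the list alone; camera adjusted p = 0.886, and adjusted p = 0.945 with an estimated correlation). The rises were 1 without control 2, knockout 1 or knockout 3 and 0 by limma without knockout 2. Of 26 p53 targets 2 rose, Sesn1 (1.31) and Trp53inp1 (0.95), and Tigar (-0.68) fell, or 1 and 1 adjusted over the list alone (camera adjusted p = 0.184, and adjusted p = 0.828 with an estimated correlation). The call of Trp53inp1 was lost without any library but control 3 (adjusted p of at most 0.141), and 1 p53 target was higher without control 2, knockout 1 or knockout 2.

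Stress and energy genes differed by group in females. Of 29 unfolded protein and integrated stress response genes 12 fell and 3 rose (15 and 3 adjusted over the list alone; camera adjusted p = 0.00389, and adjusted p = 0.711 with an estimated correlation). The camera call was lost under quantile scaling (adjusted p = 0.119). The endoplasmic reticulum chaperones Dnajb9 (-1.87) and Hspa5 (-0.78) and the factor Xbp1 (-0.68) fell, and Trib3 (0.74), Ern1 (0.52) and Sesn2 (0.49) rose. Trib3 lost its call without control 3 or any 1 knockout library, Sesn2 without control 2 or any 1 knockout library, and Ern1 without knockout 1 or knockout 2 (adjusted p of at most 0.0928). The rises were 6 without control 1, 1 without knockout 3, and 0 by limma without knockout 1 or knockout 2. Of 20 glycolysis genes 6 fell and 1 rose (6 and 2 adjusted over the list alone; camera adjusted p = 0.0169, and adjusted p = 0.828 with an estimated correlation). That camera call was lost without control 2 or knockout 3 (adjusted p = 0.0569 and 0.0705) and under quantile scaling (adjusted p = 0.0560). All 11 mitochondrially encoded genes were higher, and 7 were called (10 adjusted over the list alone; camera adjusted p = 1.55e-04, and adjusted p = 0.352 with an estimated correlation), or 4 without control 2, knockout 2 or knockout 3. Of 86 nuclear oxidative phosphorylation genes 2 fell and 1 rose (0 adjusted over the list alone; camera adjusted p = 0.923, and adjusted p = 0.988 with an estimated correlation). Without control 1 there were 15 higher and a camera call upward (adjusted p = 8.70e-04), without control 2 there was 1 lower, and without knockout 2 or knockout 3 there was no call among them. Of 23 dissociation and immediate early genes 4 fell, including Nr4a2 (-1.62), and Egr1 rose (0.93), with the same counts adjusted over the list alone (camera adjusted p = 0.0377, and adjusted p = 0.828 with an estimated correlation). That camera call was lost without control 2 or knockout 3 (adjusted p = 0.115 and 0.113) and under quantile scaling (adjusted p = 0.0560), and 2 genes fell without knockout 2.

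Immune response genes were called higher or not called in females. Of 29 interferon response genes 2 rose, Ifi35 (0.35) among them, and 0 fell by limma (1 and 0 adjusted over the list alone; camera adjusted p = 0.184, and adjusted p = 0.934 with an estimated correlation). Without control 3, 5 of the interferon genes were higher and the camera adjusted p was 0.00300. Ifi35 lost its call without control 2, control 3 or any 1 knockout library (adjusted p of at most 0.144). Without control 1, 1 interferon gene was lower. Of 17 antigen presentation genes 4 rose and 0 fell by limma, with the same counts adjusted over the list alone (camera adjusted p = 0.0111, and adjusted p = 0.352 with an estimated correlation). Among them were the immunoproteasome subunit Psmb9 (0.82) and the peptide transporter Tap2 (0.57). Its camera call was lost without control 3 (adjusted p = 0.1105). Of 9 lactogen response genes 4 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.135, and adjusted p = 0.605 with an estimated correlation). Tph1, which makes serotonin, rose 8.56-fold from 23.2 ± 8.80 to 200 ± 54.8 (SD, n = 3, adjusted p = 0.00112), and Tph2 rose too (0.93, adjusted p = 0.0580 without knockout 2). Without knockout 2, 1 lactogen gene rose, and the fall of Matn2 was not called without control 1, control 2, knockout 1 or knockout 2.

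Markers of other cells were mostly not called gene by gene in females. Of 37 acinar markers 1 fell, Bhlha15 (-2.42), and 1 rose, Dnase1 (0.89), or 1 and 0 adjusted over the list alone (camera adjusted p = 1.95e-04 downward, and adjusted p = 0.828 with an estimated correlation). Without control 2, 26 acinar markers fell and 0 rose by limma, and the rise of Dnase1 was not called without any library but control 3 (adjusted p of at most 0.0806). Of 17 duct markers 4 fell, including Cldn7 (-1.63) and Krt18 (-0.85), with the same count adjusted over the list alone (camera adjusted p = 0.135, and adjusted p = 0.828 with an estimated correlation). Camera called the list without control 2 or knockout 1 (adjusted p = 0.0155 and 0.00648). Of 12 Schwann and glial markers 1 rose and Gap43 fell (-1.02), with the same counts adjusted over the list alone (camera adjusted p = 0.722, and adjusted p = 0.934 with an estimated correlation). Of 20 stellate, fibroblast and pericyte markers Col1a1 rose (0.90), a call that was left only without knockout 2, and 0 were called adjusted over the list alone (camera adjusted p = 0.271, and adjusted p = 0.943 with an estimated correlation). No member was called, nor adjusted over the list alone, among 18 endothelial (camera adjusted p = 0.0583, and adjusted p = 0.828 with an estimated correlation), 21 macrophage (adjusted p = 0.0917 and 0.922), 17 lymphocyte (adjusted p = 0.513 and 0.945), 5 erythrocyte (adjusted p = 0.135 and 0.828) and 3 adipocyte markers (adjusted p = 0.790 and 0.943). Camera called the endothelial list without control 2, knockout 2 or knockout 3 (adjusted p = 0.00914 to 0.0267) and under quantile scaling (adjusted p = 0.0466), the stellate list without control 2 or knockout 2 (adjusted p = 0.0232 and 0.00283), the macrophage list without control 3 or knockout 3 (adjusted p = 0.00611 and 5.56e-04), the lymphocyte list without knockout 3 (adjusted p = 0.00124) and the erythrocyte list without control 1 (adjusted p = 0.0226). Among single genes, 2 endothelial markers were called without knockout 3, 2 macrophage markers without control 3 or knockout 3 and 1 without knockout 1, and 1 lymphocyte marker without control 1 or knockout 3. With an estimated correlation camera called 0 of 31 lists in females (3 at unadjusted p below 0.05), and fry called 9.

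**Figure D2:**
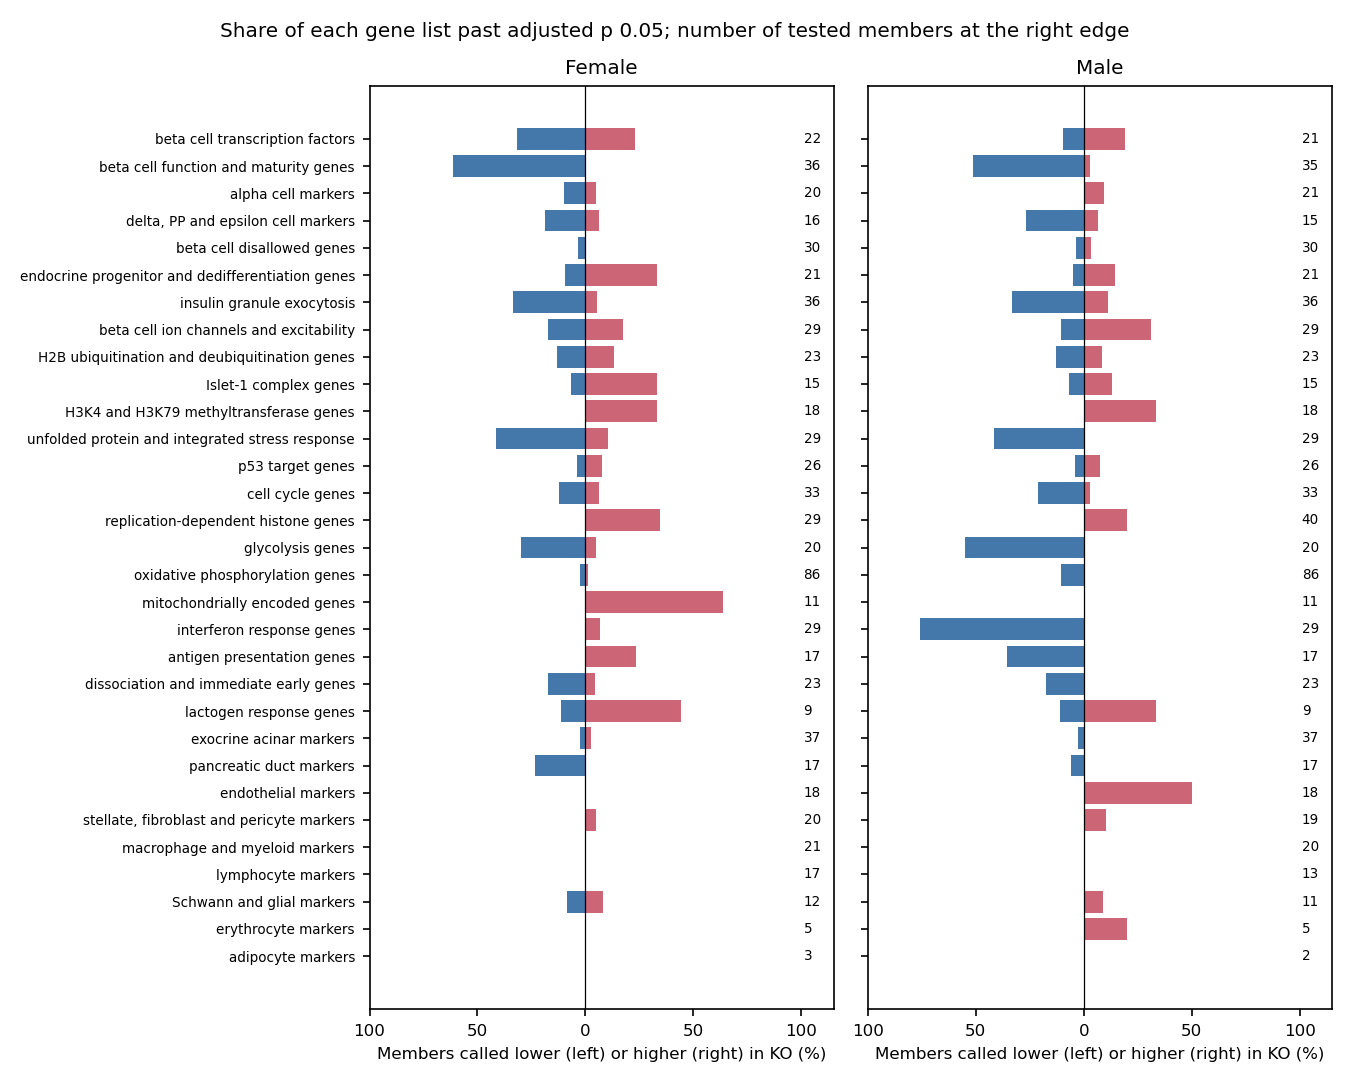
Percent of each list's tested genes (x axis) that were called lower (left bars) or higher (right bars) in the knockout, for females and males, with 1 row per gene list and the number of tested genes printed beside each bar. In males 22 of 29 interferon response genes were lower, and in females 0 by limma, where 2 were higher.

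The male comparison asked the same of males. G6pc2 fell 10.4-fold, from 73157 ± 12189 to 6986 ± 521 normalized counts (SD, n = 3 per group; log2 fold change -3.38, standard error 0.15, adjusted p = 3.24e-05). Ins1 (ENSMUSG00000035804, chromosome 19, 52252735 to 52253914) fell 4.36-fold, from 1811900 ± 386780 to 420480 ± 109410 (log2 fold change -2.12, standard error 0.24, adjusted p = 0.00179), and Ins2 was not called (log2 fold change -0.22, standard error 0.23, adjusted p = 0.565). Ucn3 fell 2.98-fold (log2 fold change -1.58, standard error 0.21, adjusted p = 0.00307). Slc2a2 fell 4.59-fold, from 4449 ± 1278 to 1121 ± 841 (log2 fold change -2.20, standard error 0.50, adjusted p = 0.0357), and its call was lost under edgeR (adjusted p = 0.0750), without the low-value filter (adjusted p = 0.0831), and without any 1 control, knockout 1 or knockout 2 (adjusted p = 0.0626 to 0.148). Sst fell 2.44-fold, from 67993 ± 15135 to 27932 ± 6785 (log2 fold change -1.29, standard error 0.21, adjusted p = 0.00602), a call lost under quantile scaling (adjusted p = 0.0655). The hormone genes Gcg (0.01, adjusted p = 0.976) and Ppy (-0.60, adjusted p = 0.198, and 0.0258 without control 2) were not called.

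In males 2372 of 18010 tested genes were called, with 1095 higher and 1277 lower. The count was 1414 without control 3 and 814 without knockout 1, while without the sparse control 2 it was 2298, of which 1849 were called with all libraries too. DESeq2 called 3733, and 880 genes, 364 higher and 516 lower, also differed at least 2-fold. Among the largest rises were Rcor2 (6.25-fold), Trpm2 (6.08-fold), H1f3 (5.24-fold), the corepressor Tle6 (5.00-fold), H2bc6 (4.71-fold) and Vwa5b1 (4.46-fold, adjusted p = 0.0713 without knockout 1). Among the largest falls besides G6pc2 were Mfsd6l (9.99-fold), Vip (log2 fold change -3.17), the orphan receptor Nr4a2 (6.95-fold), the membrane protein Ttyh1 (6.91-fold) and the cytochrome c oxidase subunit Cox6a2 (6.45-fold).

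Over the lists in males 94 of 182 called genes kept their call in every fit without 1 library. Beta cell transcription factors also went both ways in males, with 4 of 21 higher and 2 lower (5 and 4 adjusted over the list alone; camera adjusted p = 0.855, and adjusted p = 0.971 with an estimated correlation). Glis3 (1.12), Rfx3 (1.06) and Nkx6-1 (0.68) rose and St18 (-1.33) fell. The calls of Rfx3 (adjusted p = 0.0677) and St18 (adjusted p = 0.0578) were lost without knockout 1, and that of Nkx6-1 without control 1, control 2 or any 1 knockout library (adjusted p = 0.0502 to 0.0951). The rises were 2 without control 1, control 2 or knockout 3 and 1 without knockout 1. The falls were 1 without control 2, control 3 or knockout 2, none by limma without knockout 1, and 5 without knockout 3. Mafa was at 19692 ± 1863 and 20546 ± 3405 (SD, n = 3, log2 fold change 0.05, adjusted p = 0.858). Pdx1 was not called (log2 fold change -0.77, adjusted p = 0.220): knockout 3 was at 4611, above the controls at 3607 to 4295, and the other two knockouts were at 1723 and 1637, so that without knockout 3 it was called (log2 fold change -1.26, adjusted p = 0.00299). Isl1 was not called either (log2 fold change -0.50, adjusted p = 0.0806), but was without knockout 3 (adjusted p = 0.0349), under DESeq2 (adjusted p = 0.0437) and in the fit of all 12 libraries (adjusted p = 0.0243).

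Beta cell function genes fell in males, with 18 of 35 lower and 1 higher (20 and 1 adjusted over the list alone), a median log2 fold change of -0.82, and a camera call (adjusted p = 5.65e-08, and adjusted p = 0.412 with an estimated correlation). Ffar1 (-2.10), Iapp (-1.89), the prolactin receptor Prlr (-1.36) and Pcsk1 (-1.29) were among them, and the rise of Slc6a6 (0.43) was not called without any 1 library. Of 36 exocytosis genes 12 fell and 4 rose (14 and 4 adjusted over the list alone; camera adjusted p = 3.72e-04, and adjusted p = 0.421 with an estimated correlation). Syt4 (-2.21), Sv2a (-1.22) and Rab27a (-0.98) fell and Doc2b (1.44) and Snap25 (1.06) rose. Of them 7 fell without control 3 or knockout 1, and 2 rose without control 1, control 3, knockout 1 or knockout 3. Of 29 ion channel genes 9 rose and 3 fell (9 and 5 adjusted over the list alone; camera adjusted p = 0.0660, and adjusted p = 0.421 with an estimated correlation). Camera called the list without knockout 1 or knockout 2 (adjusted p = 0.0270 and 0.0370) and under quantile scaling (adjusted p = 0.0167). Trpm2 (2.60) and the inositol trisphosphate receptor Itpr1 (1.36) rose and Kcnj11 (-1.13) fell, with 5 higher and 1 lower without knockout 1. The acinar markers had a median log2 fold change of 0.18 in males (-0.85 without control 3 to 1.07 without control 1, and 0.40 under quantile scaling). The endothelial markers had 0.60 (0.50 without knockout 2 to 0.70 without knockout 1) and the stellate markers 0.54 (0.29 without control 3 to 0.96 without control 1). The 5 erythrocyte markers had 1.45 (1.06 without control 3 to 1.83 without knockout 3), and the macrophage markers had 0.18 (-0.09 without control 3 to 0.33 without control 1).

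Other endocrine groups had few calls in males. Of 21 progenitor and dedifferentiation genes 3 rose and 1 fell (5 and 1 adjusted over the list alone; camera adjusted p = 0.365, and adjusted p = 0.767 with an estimated correlation), with 1 higher without knockout 1 or knockout 2. Runx1t1 rose (1.45), and Pax4 was at 0, 0 and 1.44 in controls and at 54.4, 29.0 and 19.2 in knockouts, a call left only without control 2 (adjusted p of at most 0.287). The call of Asb11 (-4.15) was lost without any 1 control or without knockout 1 (adjusted p = 0.0535 to 0.0793). Of 30 disallowed genes Igfbp4 rose (2.01) and Acot7 fell (-1.01), or 1 and 0 adjusted over the list alone (camera adjusted p = 0.855, and adjusted p = 0.971 with an estimated correlation). Acot7 lost its call without any library but knockout 2 (adjusted p = 0.0589 to 0.181) and without the low-value filter (adjusted p = 0.0507), and 3 disallowed genes rose without control 1 and 2 fell without knockout 2. Of 21 alpha cell markers Slc7a2 (0.79) and Slc38a5 (0.86) rose and 0 fell by limma, with the same counts adjusted over the list alone (camera adjusted p = 0.569, and adjusted p = 0.767 with an estimated correlation). Slc7a2 lost its call without control 2, control 3, knockout 1 or knockout 3 (adjusted p = 0.0701 to 0.104) and Slc38a5 without control 1, control 3, knockout 1 or knockout 2 (adjusted p = 0.0577 to 0.149). In the list 1 alpha marker fell without control 2, and 3 rose without knockout 3. Of 15 delta, PP and epsilon markers 4 fell and 1 rose (4 and 2 adjusted over the list alone; camera adjusted p = 0.501, and adjusted p = 0.767 with an estimated correlation). The opioid precursor Pdyn (-2.34) and Sst were among the falls and Tacr3 (2.73) rose. The falls were 2 without control 3 or knockout 1 and the rises 2 without control 1 or control 2.

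The same lists were tested in males. Of 18 genes of methyltransferases and their partners 6 rose and 0 fell by limma (7 and 0 adjusted over the list alone). Camera gave adjusted p = 0.00104, and adjusted p = 0.412 with an estimated correlation. The rises were the methyltransferase genes Kmt2c (1.25) and Kmt2a (1.16) and the partner genes Kdm6a, Mllt3, Mllt10 and Rbbp5. They numbered 3 without control 1 or control 3 and 2 without knockout 1 or knockout 3. Of 40 histone genes 8 rose and 0 fell by limma (11 and 0 adjusted over the list alone; camera adjusted p = 1.63e-06, and adjusted p = 0.412 with an estimated correlation). Among them were H3c15 (2.65), H1f3 (2.39), H1f4 (2.32) and H4c8 (2.08), and 12 rose without control 2. Of 33 cell cycle genes 7 fell and Mybl2 rose (9 and 2 adjusted over the list alone; camera adjusted p = 3.43e-04, and adjusted p = 0.421 with an estimated correlation). They included Top2a (-1.75, adjusted p = 0.0550 without control 3), Mcm2 (-1.02, adjusted p = 0.0633 without knockout 1) and Pcna (-0.89). The falls were 4 without control 1, knockout 2 or knockout 3, 3 without control 3 and 2 without knockout 1. The call of Mybl2 (1.21) was lost without control 1 or any 1 knockout library (adjusted p of at most 0.127). Of 15 Islet-1 complex genes Ldb1 (0.65) and Ssbp2 (0.66) rose and the LIM protein Lmo1 fell (-1.39), or 4 and 4 adjusted over the list alone (camera adjusted p = 0.819, and adjusted p = 0.918 with an estimated correlation). Both rises were lost without control 1, control 2, knockout 1 or knockout 2 (adjusted p = 0.0511 to 0.118), and 2 of the list's genes fell without knockout 2 or knockout 3. Of 23 H2B ubiquitination genes 3 fell, Rnf20, Leo1 (-0.69) and Eny2 (-0.58), and 2 rose (4 and 2 adjusted over the list alone; camera adjusted p = 0.855, and adjusted p = 0.971 with an estimated correlation). Leo1 lost its call without control 3 or knockout 1 (adjusted p = 0.0655 and 0.0762) and Eny2 without control 1, control 3, knockout 1 or knockout 2 (adjusted p of at most 0.112). The rises were 0 by limma without control 1, control 3, knockout 1 or knockout 2 and 1 without control 2 or knockout 3. Of 26 p53 targets Sesn1 (1.68) and Trp53inp1 (0.83) rose and Tigar (-0.78) fell, with the same counts adjusted over the list alone (camera adjusted p = 0.516, and adjusted p = 0.757 with an estimated correlation). Trp53inp1 lost its call without knockout 1 or knockout 3 (adjusted p of at most 0.0852), and 2 p53 targets fell without knockout 2.

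Stress and energy lists were also tested in males. Of 29 unfolded protein and integrated stress response genes 12 fell and 0 rose by limma (14 and 0 adjusted over the list alone; camera adjusted p = 1.22e-08, and adjusted p = 0.412 with an estimated correlation). Among them were Dnajb9 (-2.26), Xbp1 (-1.03), Trib3 (-1.02) and Atf4 (-0.86), and 7 fell without knockout 1. Of 20 glycolysis genes 11 fell and 0 rose by limma (12 and 1 adjusted over the list alone; camera adjusted p = 4.55e-07, and adjusted p = 0.421 with an estimated correlation). Pfkp (-1.77), Pgk1 (-1.33) and Gapdh (-1.27) were among them, with 7 lower and 1 higher without control 3, 5 without knockout 1 and 6 without knockout 3. Of 86 oxidative phosphorylation genes 9 fell and 0 rose by limma, with the same counts adjusted over the list alone (camera adjusted p = 0.00715, and adjusted p = 0.421 with an estimated correlation). Atp5g1 (-1.09) was among them, with 5 lower without control 1, knockout 2 or knockout 3 and 4 without control 3 or knockout 1. No mitochondrially encoded gene of 11 was called, nor adjusted over the list alone, and 10 were higher (camera adjusted p = 0.194, and adjusted p = 0.796 with an estimated correlation). Without knockout 2 the camera call was reached (adjusted p = 0.00902) with 2 genes. Of 23 dissociation and immediate early genes 4 fell, Nr4a2 (-2.80) and Fos (-2.29) among them, and 0 rose by limma, with the same counts adjusted over the list alone (camera adjusted p = 5.64e-05, and adjusted p = 0.421 with an estimated correlation), or 2 without knockout 1 and 7 without knockout 2.

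Interferon response genes, which cells raise against viruses, fell in males. Of 29 tested 22 fell and 0 rose by limma (27 and 0 adjusted over the list alone), all 29 were lower, and the median log2 fold change was -1.11 (camera adjusted p = 2.09e-18, and adjusted p = 0.412 with an estimated correlation). The chemokine Cxcl10 fell 4.24-fold, from 3924 ± 550 to 953 ± 311 (SD, n = 3, adjusted p = 0.00173), and Ifit1 (-1.98), Rsad2 (-1.88), the regulator Irf7 (-1.73) and Isg15 (-1.61) were among the others. Of 17 antigen presentation genes 6 fell and 0 rose by limma (7 and 0 adjusted over the list alone; camera adjusted p = 0.00129, and adjusted p = 0.504 with an estimated correlation). These were Tap1 (-1.03), Psmb8 (-0.93), B2m (-0.83), H2-Q4 (-0.83), H2-K1 (-0.75) and H2-D1 (-0.68, adjusted p = 0.0739 without knockout 1). Ifit3 and Ifit3b, and the H2-Q genes, share sequence, and the annotated spans of Tap1 and Psmb9 overlap, with the strand of the reads not stated. Of 9 lactogen response genes 3 rose and 1 fell (4 and 2 adjusted over the list alone; camera adjusted p = 0.442, and adjusted p = 0.767 with an estimated correlation). Tph1 rose (3.47 as the difference of mean log2 values), with group means of 44.6 and 320 normalized counts (adjusted p = 0.0201). Its call was lost without control 3, knockout 1 or knockout 3 (adjusted p of at most 0.0955). There were 2 lactogen genes lower without control 1 or knockout 2 and 1 higher without knockout 1.

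Endothelial markers stood out among the other cells in males. Of 18 tested 9 rose and 0 fell by limma (12 and 0 adjusted over the list alone; camera adjusted p = 2.18e-06, and adjusted p = 0.421 with an estimated correlation). Among them were Emcn (1.18), Ptprb (1.02) and the receptor Kdr (0.91), and 5 rose without control 2, control 3 or knockout 1 and 3 without knockout 2 or knockout 3. Of 19 stellate, fibroblast and pericyte markers Col6a3 (1.08) and Pdgfrb (0.86) rose and 0 fell by limma (5 and 1 adjusted over the list alone; camera adjusted p = 0.0323, and adjusted p = 0.740 with an estimated correlation). That camera call was lost without control 3, knockout 1 or knockout 2 (adjusted p = 0.0503 to 0.196). Col6a3 lost its call without any library but control 1, and Pdgfrb without control 3 or any 1 knockout library (adjusted p of at most 0.157). The stellate rises were 4 without control 1, 1 without control 3 and 0 by limma without any 1 knockout library, and 1 gene fell without knockout 2. Of 5 erythrocyte markers Hba-a1 rose (1.45), or 2 adjusted over the list alone (camera adjusted p = 0.0204, and adjusted p = 0.580 with an estimated correlation). That camera call was lost without control 3, knockout 1 or knockout 2 (adjusted p = 0.0508 to 0.0755), and the rise of Hba-a1 without control 2, control 3, knockout 1 or knockout 2, while 3 erythrocyte genes rose without knockout 3. Of 37 acinar markers Bhlha15 alone was called (-2.48), lower (1 adjusted over the list alone; camera adjusted p = 0.855, and adjusted p = 0.971 with an estimated correlation). There was a camera call upward without control 1 (adjusted p = 0.00627), downward without control 3 (adjusted p = 1.51e-04), and 1 gene higher without control 2. Of 17 duct markers Cldn7 alone was called (-2.03), lower (1 adjusted over the list alone; camera adjusted p = 0.365, and adjusted p = 0.767 with an estimated correlation). There were 2 lower without knockout 2 and a camera call without control 3 (adjusted p = 0.0456). Of 11 Schwann and glial markers 1 rose, 1 also adjusted over the list alone (camera adjusted p = 0.569, and adjusted p = 0.918 with an estimated correlation), a call left only without control 2, and 1 fell without knockout 2. No member was called, nor adjusted over the list alone, among 20 macrophage (camera adjusted p = 0.722, and adjusted p = 0.971 with an estimated correlation) and 13 lymphocyte markers (adjusted p = 0.855 and 0.971), with 1 lymphocyte gene lower only without control 3. Adipocyte markers had 2 tested members, too few for a list test, and neither was called. With an estimated correlation camera called 0 of 30 lists in males (3 at unadjusted p below 0.05), and fry called 10.

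The last comparison asked whether the knockout effect differed between the sexes, over 17330 genes tested in both. Of 1771 genes higher in females and 1092 in males 701 were shared, against 112 by chance (odds ratio 25.4), and of 1928 and 1276 lower genes 834 were shared, against 142 (odds ratio 25.8). Glis3, Rcor2 and Tph1 were among the shared rises, and G6pc2, Ins1, Sst and Dnajb9 among the shared falls. Another 12 genes were higher in females and lower in males, and 0 had limma calls the other way. Across genes, which are not independent replicates, the log2 fold changes had a Pearson r of 0.579 and a Spearman rho of 0.572, and 93.0% of the 4520 genes called in either sex had the same sign.

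The effect itself differed between the sexes for 19 genes (1409 at unadjusted p below 0.05), all with a lower value in males. They were Steap1, H2-Q4, Tap1, Shmt2, Pycr1, Serpini1, Cyb5r1, H2-T22, Apol9b, Ppp1r15a, Cxcl10, Trafd1, Gtpbp2, Tmed3, Phf10, Trib3, Gbp5, Ogfr and Niban1. Interferon-inducible genes among them were Cxcl10 (log2 fold change 0.39 in females and -2.08 in males, difference -2.47, standard error 0.37, adjusted p = 0.0310), Tap1 (0.28 and -1.03, difference -1.31, adjusted p = 0.0226) and H2-Q4 (0.29 and -0.83, difference -1.11, adjusted p = 0.0226). The mitochondrial serine and proline enzymes Shmt2 (0.25 and -1.17, difference -1.43) and Pycr1 (0.52 and -1.13, difference -1.65), and the stress genes Trib3 (0.74 and -1.02) and Ppp1r15a (0.23 and -1.50), went the same way. In females the call of Pycr1 was lost without any library but control 1 (adjusted p = 0.0605 to 0.149) and under edgeR (adjusted p = 0.0509) or TMM scaling (adjusted p = 0.0510), H2-Q4 was called under quantile scaling (adjusted p = 0.0304), and Shmt2 was called without control 1 (adjusted p = 0.0188). The count was 0 by limma with the replicate number as a block. It was also 0 by limma without female control 2, any 1 female knockout, male control 3, male knockout 1 or male knockout 3. Without male control 1 it was 53. DESeq2 called 238 genes, 59 with a higher and 179 with a lower value in males, voom called 31 and edgeR 20. The differences in Mafa (log2 difference 1.27, adjusted p = 0.262), Ins1 (-1.05, adjusted p = 0.351) and G6pc2 (-0.63, adjusted p = 0.507) were not called.

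Camera on the difference called 11 of 30 lists. The interferon response list (median log2 difference -1.45, camera adjusted p = 1.82e-39, and adjusted p = 0.0487 with an estimated correlation) and the antigen presentation list (-0.76, camera adjusted p = 3.75e-13, and adjusted p = 0.0487 with an estimated correlation) were called with either correlation and by fry. Both were lower in males than in females, where Psmb9 rose. The other called lists held with the preset correlation alone, at adjusted p = 0.448 or more with an estimated correlation: cell cycle genes (-0.81), glycolysis genes (-0.43), immediate early genes (-0.34), the unfolded protein list (-0.23), oxidative phosphorylation (-0.11), p53 targets (-0.11), acinar (1.13), macrophage (0.61) and endothelial markers (0.45). Each sex was scaled apart, so a difference in scaling between the sexes falls with sex and not with its knockout effect.

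**Figure D3:**
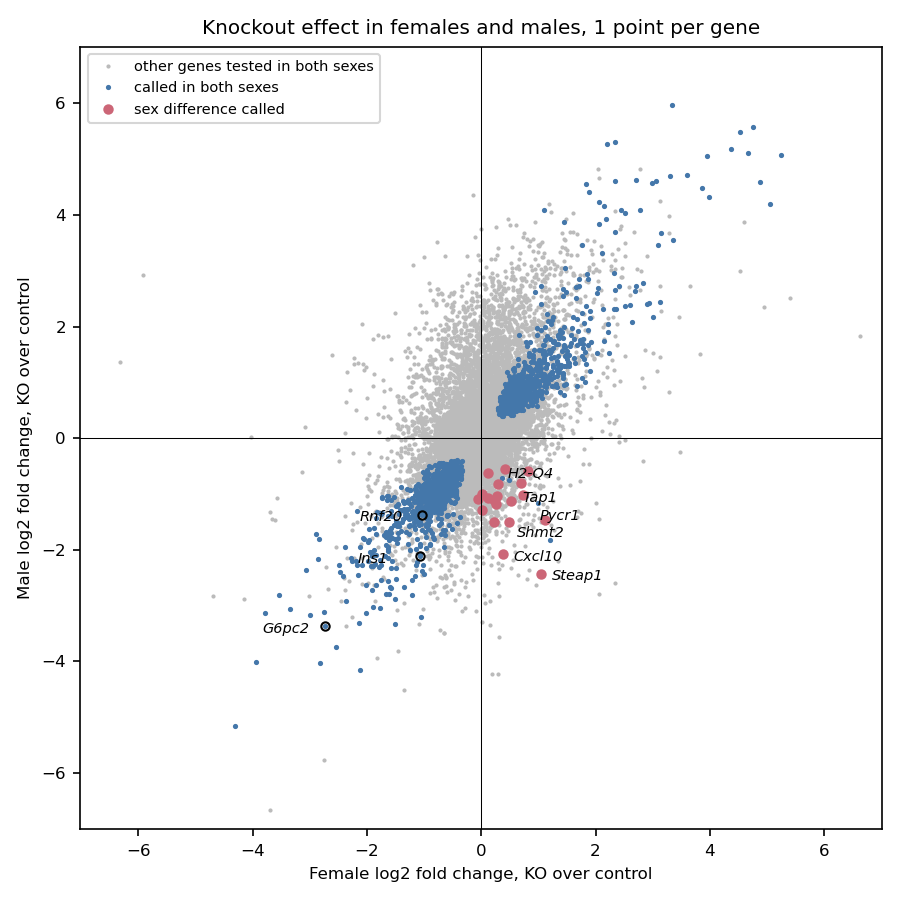
Log2 fold change of knockout over control in females (x axis) and males (y axis), with 1 point per gene tested in both sexes: grey, other genes; blue, genes called in both; red, the 19 genes with a called sex difference. Pearson r across genes was 0.579.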

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

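The splits of the libraries within each sex were set before the results were seen, while the list tests of the sex difference, its splits and the tests of explanations for the 3 patterns below were chosen only after.

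What drew attention here was a tested difference between the sexes. The knockout effect differed for 19 genes. In 2 of 100 labellings of sex within genotype, the real one included, as many genes were called after each sex's gene mean was removed. A version with the mean kept gave 4 of 100, and the mean was removed after that was seen. Both shares lie below 0.05, but they do not exclude chance, since the second version was chosen after the first was seen. The count was also 0 by limma with the replicate number as a block, and without any 1 of several libraries named above. The highest other labelling called 82 genes (89 with the mean kept), several times the real count. It was the real labelling with female control 1 and the sparse male control 2 exchanged. Without female control 1 the count was 20, and without male control 2 it was 18. The 82 calls may point to a structure of the samples, which was not tested. The named genes had a lower effect in males than in females, with log2 differences of -2.47 for Cxcl10, -1.31 for Tap1, -1.11 for H2-Q4, -1.43 for Shmt2 and -1.65 for Pycr1. The lists were called by camera with a median difference of -0.23 (unfolded protein response), -0.11 (p53 targets), -0.81 (cell cycle), -0.43 (glycolysis), -0.11 (oxidative phosphorylation), -1.45 (interferon response), -0.76 (antigen presentation), -0.34 (immediate early genes), 1.13 (acinar), 0.45 (endothelial) and 0.61 (macrophage), and with an estimated correlation for the interferon and antigen lists alone.

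Within each sex the 10 splits of 6 libraries are too few for a share under 0.05. In females 1 of 10 splits, the real one, gave 3745 called genes and the highest other gave 1, and in males 1 of 10 gave 2372 and the highest other 2.

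Of the genes of beta cell function, 22 of 36 in females and 18 of 35 in males were called lower, and camera called the list with the preset correlation but not with an estimated one (adjusted p = 0.352 and 0.412). A lower share of beta cells alone would raise the other endocrine hormones alike. Relative to Gcg, Sst changed by log2 -1.14 in females (standard error 0.36) and by -1.30 in males (standard error 0.31). Without 1 library at a time these ran from -0.88 to -1.51 and from -0.95 to -1.59. This argues against a lower share as the sole change in the islets. A fall of Sst within delta cells would give the same values, so they do not decide whether a lower share lowered beta cell genes. A difference in acinar RNA is argued against in females, since the median of the list was -0.99 with the acinar level as a covariate and 19 of its genes were called lower. In males the endothelial (median 0.60) and stellate markers (0.54, and 0.29 without control 3 to 0.96 without control 1) were higher, as a lower share would need. Gcg was at 0.01 in males. In females the endothelial markers were higher too (0.24, and 0.12 without knockout 1 to 0.31 without knockout 3), while acinar (-1.01) and macrophage markers (-0.48) were lower. With a lower share, beta cell transcription factors would fall too, as far as beta cells alone express them. Their medians were 0.10 in females (-0.04 to 0.18 without 1 library at a time) and -0.01 in males (-0.09 to 0.06). Alpha markers would rise, and had medians of 0.02 in females (-0.09 to 0.21) and 0.11 in males (-0.03 to 0.20). These lists do not show a lower share, while the endothelial markers go with it. A lower share may still contribute, together with a change of Sst within delta cells. An effect of the Cre transgene, which falls with the genotype, and loss of Rnf20 in the beta cells stay open as hypotheses.

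Of the interferon response genes, 22 of 29 were called lower in male knockouts, and camera called the list with the preset correlation but not with an estimated one (adjusted p = 0.412). The sparse male control 2 is argued against as the cause, since the median of the list was -1.10 without it, with 21 genes called lower. Fewer macrophages are argued against, since their 20 markers had a median of 0.18 (standard error over genes 0.21), and -0.09 to 0.33 without 1 library at a time. Fewer lymphocytes stay open, since their 13 markers had a median of -0.32 (standard error over genes 0.32), which ran from -1.17 without knockout 1 to 1.08 without control 1. Genes of a list are not independent, so the standard errors over genes can be too small. Handling or a batch that differed between the male groups cannot be told apart from the genotype: immediate early genes were lower (median -0.57, from -0.82 without knockout 2 to -0.32 without knockout 3, camera adjusted p = 0.421 with an estimated correlation), no batch is labelled, and infection, housing, the Cre transgene and the genotype itself were not tested.

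Of the replication-dependent histone genes, 10 of 29 in females and 8 of 40 in males were called higher, and camera called the list with the preset correlation but not with an estimated one (adjusted p = 0.631 and 0.412). More dividing cells are argued against, since the cell cycle median minus the histone median was -0.86 in females and -2.29 in males. The standard errors, 0.24 and 0.32, run over genes, which are not independent. Without 1 library at a time the cell cycle median ran from -0.30 to 0.19 in females and from -0.98 to -0.54 in males. The histone median ran from 0.50 to 1.22 in females and from 1.02 to 2.07 in males. Low values on the log scale are argued against, since edgeR on the recovered reads called 11 histone genes higher in females and 9 in males. The sparse male control 2 is argued against as the sole cause, since 12 were called higher without it. The male median was 1.55 with all libraries and 1.02 without control 2, the lowest of the fits without 1 library. That library may therefore add to the size of the male rise. Polyadenylated histone transcripts, a difference in library preparation and reads shared between histone genes were not tested. No other biological explanation was tested.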

How the results depend on the processing

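The edgeR fits were chosen after the results were seen, and the other alternatives here were set before the data were examined. Female calls numbered 3745, and 1118 at 2-fold, 2408 in a fit of all 12 libraries and 2339 with the acinar level as a covariate. Their other alternatives gave 3209 to 4371. Male calls numbered 2372, and 880 at 2-fold, 3733 with DESeq2 and 4396 with all 12 libraries, against 2062 to 2635 otherwise. A 2-fold threshold can only remove calls. In the fit of all 12 libraries 1 spread replaces that of each sex, and only the 17330 genes tested in both were fitted. These 2 changes were not separated. The cause was not tested for the acinar covariate and DESeq2. On simulated data, where far fewer genes were changed, DESeq2 made the most false calls. The sex difference, 19 genes, was 38 with quantile scaling, 238 with DESeq2 and 31 with voom, where the cause was not tested, and 18 to 20 with TMM, edgeR, no filter or other pseudocounts. At 2-fold the overlaps were 207 higher and 209 lower genes in place of 701 and 834. The correlation of fold changes, 0.579, was 0.464 with no filter, which adds genes with few reads, and 0.811 over genes called in either sex.

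Without 1 library at a time the counts ran from 1847 to 3760 in females, from 814 to 2298 in males and from 0 to 53 for the sex difference, and the correlation from 0.491 to 0.609. Rnf20 was called under every alternative, with log2 values of -1.11 to -0.98 in females and -1.45 to -1.32 in males. With an estimated correlation camera called 0 lists in females and 0 in males, in place of 11 and 14 (3 in each sex at unadjusted p below 0.05; fry called 9 and 10). The oxidative phosphorylation list in females had camera adjusted p from 8.70e-04, upward without control 1, to 0.808 without knockout 2, and its direction was down with all libraries. The acinar list in males had adjusted p from 1.51e-04, downward without control 3, to 0.835 without knockout 1, against an upward direction with all libraries. The cause was not tested for either.

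With the replicate number as a replicate block, 3209 genes were called in females, 2062 in males and 0 for the sex difference by limma (without the block, 1409 at unadjusted p below 0.05 and 20 to 238 called by edgeR, voom and DESeq2). In females the numbers do not pair the libraries: deviations of libraries with the same number correlated at -0.0408, -0.276 and -0.135. Female control 2 correlated best with knockout 3 (0.248). In males the deviations correlated at 0.121, 0.00966 and 0.153 for the same number, against -0.159 to 0.0843 for unlike numbers. A weak pairing is therefore not excluded in males, although the labels name none and the descriptions number some libraries differently from the titles. Under the block 2 list calls in females and none in males changed, as did 3 calls of named genes in each sex, and the camera counts of 11 and 14 did not.

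Of the list results under leaving out 1 library, 165 in females and 168 in males kept their direction and side of the threshold, 8 and 6 lost a call, 12 and 5 gained one and 1 in each reversed. For named genes these were 306 and 288 kept, 22 and 39 lost and 2 and 3 gained. Under the other alternatives 106 and 105 list results were kept, 16 and 14 lost, mostly with the estimated correlation, and 2 and 1 gained. For named genes 639 and 651 were kept, 18 and 7 lost and 1 and 2 gained. Depth limits genes with few reads. Male control 2 had 1596 tested genes without reads, more than its depth accounts for, since other male libraries would keep 21496 to 22666 genes at that depth against its 17701.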

Other observations

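The test on gene length was set before the data were examined, and the tests on Tph1 and the values by length were chosen after the results were seen.

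Called genes with a long span were more often higher than lower in the knockout, and those with a short span more often lower, although most genes were not called. Among the 4501 male genes with the longest span (median 98.3 kb) 637 were called higher and 205 lower, and among the 4502 shortest (median 2.83 kb) 52 and 335. Without knockout 1 these were 208 and 71 against 12 and 143. In females they were 680 and 453 against 250 and 386, and without knockout 2 they were 315 and 249 against 103 and 220. The median log2 fold change of the longest genes was 0.23 in males and 0.05 in females, and that of the shortest -0.06 in both. In females these were 0.00 and -0.01 without control 1, where 579 of the longest were called higher and 554 lower.

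The receptor for prolactin fell in both sexes, with Prlr at log2 -1.30 in females and -1.36 in males. Tph1, which lactogens raise in islets, rose instead (in males its call was lost without control 3, knockout 1 or knockout 3, at adjusted p of at most 0.0955), while Cish and Socs2 were not called.

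A hypothesis was that long genes would fall more, if loss of H2B ubiquitination slowed elongation. The test showed the opposite sign: the Spearman rho of span with log2 fold change across genes was 0.123 in males and 0.0815 in females, and 0.00315 to 0.127 in females and 0.0957 to 0.186 in males without 1 library at a time. These values argue against that hypothesis for steady transcript levels. Differences in RNA integrity between the groups could also tilt values by length, and they were not tested.

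A second hypothesis was that Tph1 rose from lactogen signalling by a growth hormone sequence in the Cre transgene, which the labels neither name nor exclude. Such signalling may raise Cish and Socs2 as well. Their mean log2 change was 0.0164 in females (standard error 0.12) and 0.33 in males (standard error 0.19). Neither value showed a clear rise, but the test as set would have counted against the hypothesis only if this mean fell. The hypothesis is left undecided, and since no control is labelled with Cre it cannot be told apart from the genotype.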
